A study of Mus musculus with 6 samples.

How the data were processed

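Total RNA from mpkCCD clone 11 cells was measured on Affymetrix Mouse Genome 430 2.0 arrays, 3 for vehicle and 3 for dDAVP (0.1 nM, 5 days), 1 array per sample. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled cRNA was made by the manufacturer's standard method. The submitters' processing notes name MAS5, RMA and Affymetrix Expression Console 1.1, with no role or order. The authors deposited log2 signals, 1 value per probe set and array, and which of the named methods produced them is not given in the sources used here. The values run from 2.15 to 14.1 with no missing value and with array medians within 0.043 log2 units of each other, so they were taken as already summarised and normalized between arrays. Background correction and summary over probes can compress the ratios of dim probe sets, so the folds of dim genes may be understated. The table held 28287 probe sets, and any filter applied before deposition is not given in the sources used here. The number of arrays limits the precision, and no read depth applies.

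Groups and replicate numbers came from the sample titles, and all 6 columns of the table were used. The 62 Affymetrix control probe sets were left out of the test and used only as checks. Probe sets were named from the platform annotation: 23097 had 1 gene symbol, 611 had several and 4517 had none, and no gene was named from a probe set with several. Of the first kind, 23026 were matched by Entrez gene ID to a mouse RefSeq gene table (assembly GRCm38.p6, used only for names and for the order of genes), which changed 0 symbols. The sources used here name no genome build for the arrays, so no coordinates are given.

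dDAVP and vehicle arrays were compared in limma 3.58.1 under R 4.3.3 with lmFit and eBayes (default prior, 4 residual degrees of freedom) on the values as deposited, over 28225 probe sets. P-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. A gene was represented by its probe set with the highest mean over all 6 arrays, and it changed if that probe set did. Standard errors and 95% intervals are those of the moderated fit, and SDs are over the 3 arrays of a group. Measures with 1 value per array were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1.

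A total of 28 lists were fixed before the data were examined, 22 of pathways and functions and 6 of markers of other cell types, with 582 of 757 list entries measured. Lists were tested with camera at a preset inter-gene correlation of 0.01 on 1 probe set per gene, with adjustment over the 28 lists, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. Genes named in the text were chosen by a rule also fixed before the data were examined: Aqp2, Aqp3, Scnn1a, Scnn1b, Scnn1g and Avpr2 whatever their values, then among changed genes whose groups did not overlap the 12 with the largest increase and the 12 with the largest decrease (4 passed), and in each list that was called or held at least 3 changed members up to 4 changed members. That rule gave 25 genes, and others are said to have been chosen after their values were seen. The tests, the lists, the naming rule and the alternatives were set before the data were examined, with these exceptions. The scalings to hybridisation or poly-A controls, the lowering of the dDAVP arrays by 0.146 log2 units and the count of genes by any changed probe set came after. So did the tests of explanations that the closing section says were chosen after the result was seen.

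The code was tested on simulated data for the comparison of dDAVP with vehicle, with 200 of 28225 probe sets changed in each of 10 runs. Levels were those of the 6 arrays, and the spread of each probe set was its moderated residual variance, drawn towards a common value. It recovered 13.2% of changes of 0.3 log2 units, 78.8% of 0.5, and 100% of 1 and of 2, and 5.99% of the calls were false. With no simulated effect there were 0 calls of probe sets and at most 2 calls of lists, and 2 of 2 lists shifted by 0.1 were called. The simulated probe sets varied independently of each other. In the real arrays the estimated inter-gene correlation of the shifted lists was 0.088 (mitosis) and 0.14 (sterol synthesis). The simulation therefore cannot give the rate of false list calls in the real data.

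Alternatives were quantile normalization, centring on the array median, 2 filters on dim probe sets (above the median of all probe sets, or above the 95th percentile of olfactory receptor probe sets, which kidney cells were assumed not to express), a trended and a robust prior, the replicate number as a block, leaving out each array, a threshold of 0.01, an added 1.5-fold minimum, the mean of a gene's probe sets, and the set tests above. The 10 olfactory receptor probe sets had a mean of 3.18 and a highest value of 3.56, and 3048 probe sets lay below their 95th percentile. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.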

Results

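Gene expression was measured in mpkCCD clone 11 cells, an immortalised mouse line from the cortical collecting duct of the kidney that keeps the vasopressin-regulated water channel aquaporin 2. The cells formed a polarized layer on a membrane support. After the layer had reached an electrical resistance of at least 5 kohm per cm2 they received 0.1 nM dDAVP or vehicle for 5 days. dDAVP, or desmopressin, is a synthetic vasopressin analog that acts on the V2 receptor. The labels name vasopressin-mediated expression of endogenous aquaporin 2 as the subject. The 1 comparison in the design, dDAVP against vehicle, asks which transcripts differ after this long exposure. Each group had 3 Affymetrix Mouse Genome 430 2.0 arrays of total RNA, which the labels call biological replicates. Whether they came from separate passages or days is not given, so the p-values measure the spread between these 6 samples. The table held 28225 probe sets other than controls, of which 23097 carried the name of exactly 1 gene and covered 12364 genes. Array medians lay within 0.043 log2 units of each other, and the correlation across probe sets between any 2 arrays was 0.996 to 0.998.

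The 3' signal of beta-actin exceeded its 5' signal by 0.70 ± 0.017 log2 units in vehicle arrays and by 0.69 ± 0.021 in dDAVP arrays (SD, n = 3, exact two-sided permutation p = 0.6). For Gapdh the excess was 0.083 ± 0.025 and 0.11 ± 0.046 (exact p = 0.6). The mean of the hybridisation controls, bacterial and phage transcripts added to the labelled material, was 10.61 ± 0.080 log2 units in vehicle arrays and 10.46 ± 0.066 in dDAVP arrays (exact p = 0.1, the smallest that 3 against 3 arrays allow). The poly-A controls, added to the RNA before labelling, were at 8.10 ± 0.10 and 8.12 ± 0.019 (exact p = 0.8).

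Aqp2, which encodes the apical water channel that vasopressin regulates in principal cells, rose 17.8-fold with dDAVP (95% interval 16.1 to 19.7). Its only probe set measured 6.70 ± 0.042 log2 units in vehicle cells and 10.85 ± 0.072 in dDAVP cells (SD, n = 3, limma adjusted p = 1.66e-07). The fold of the next gene, by its brightest probe set, was 3.51. Avpr2, the V2 receptor through which dDAVP acts, rose 1.44-fold (8.73 ± 0.072 to 9.25 ± 0.053, adjusted p = 0.0271). Pde4b, a phosphodiesterase that breaks down cAMP, rose 3.51-fold (adjusted p = 9.74e-04) on its brightest probe set. On dimmer Pde4b probe sets that also passed, the rises were 4.46-fold and 5.23-fold. The apical sodium channel of the same cells did not pass the test. The log2 change was 0.02 ± 0.074 (SE) for its alpha subunit Scnn1a, 0.23 ± 0.11 for Scnn1b and 0.26 ± 0.074 for Scnn1g. The basolateral water channel gene Aqp3 did not pass it either, at 0.15 ± 0.079 (adjusted p = 0.703). Leaving out any 1 of the 6 arrays ended the call of Avpr2, whose log2 change then lay between 0.48 and 0.55, while Aqp2 and Pde4b passed in each such fit. Scaling to the poly-A controls, a setting chosen after the data were seen, also ended the Avpr2 call (0.50, adjusted p = 0.0888).

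In all, 36 genes changed at a Benjamini-Hochberg adjusted p below 0.05 in limma, 32 higher and 4 lower with dDAVP. The count fell when any 1 array was left out and rose with a trended prior, as given below. The split into higher and lower genes depends on the scaling of the arrays. With the dDAVP arrays lowered by 0.146 log2 units, the change of the poly-A controls plus 2 SE and a setting chosen after the data were seen, 24 genes were higher and 21 lower. At least 2-fold changes were seen in 12 of the higher genes and 1 of the lower genes as deposited. After that lowering they were seen in 6 higher genes and 1 lower gene. After Aqp2 and Pde4b, the largest rises were in the cytosolic sulfotransferase Sult1d1 (3.33-fold, 4.92 ± 0.078 to 6.66 ± 0.084), the gasdermin Gsdmc2 (3.16-fold, 7.13 ± 0.046 to 8.79 ± 0.24) and the magnesium transporter family member Nipal1 (2.53-fold, 7.03 ± 0.043 to 8.37 ± 0.13). Fcgbp, a large secreted protein found in mucus, rose 2.26-fold. B3gnt7, a glycosyltransferase that extends carbohydrate chains, rose 2.17-fold. Selenop, a secreted selenium carrier, rose 2.16-fold. Sprr1a, a small proline-rich protein first known from cornified epithelia, rose 2.13-fold. The last 3 of the 12 were the death-domain receptor Tnfrsf21 (2.05-fold), the keratin Krt23 (2.04-fold) and Tmem178 (2.01-fold). The limma adjusted p of these 10 genes ranged from 1.81e-04 for Sult1d1 to 0.0271 for Krt23. Gsdmc2 belongs to a family of closely related mouse genes, and whether its probe set tells them apart was not tested.

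The 4 genes that fell were Antxr1, a membrane receptor that binds extracellular matrix, Rasl11a, a small GTPase of the Ras family, Fras1, a basement membrane protein, and P3h2, a collagen prolyl hydroxylase. Antxr1 had 0.393 of its vehicle signal (5.67 ± 0.098 to 4.32 ± 0.17, adjusted p = 0.00165), Rasl11a 0.607 (adjusted p = 0.00672), Fras1 0.644 (adjusted p = 0.0243) and P3h2 0.709 (adjusted p = 0.0209). A second Antxr1 probe set, dimmer by its mean, changed by 0.09 ± 0.067 (SE) and did not pass. Of the 4 Pde4b probe sets 3 rose and the dimmest, at a mean of 3.60, changed by -0.04 ± 0.070. For Fras1 both probe sets fell, and for Nipal1 and Sult1d1 both rose. No gene had changed probe sets in opposite directions (count 0). Leaving out any 1 array ended the calls of Fras1 (log2 change -0.69 to -0.56) and P3h2 (-0.52 to -0.48). Scaling to the hybridisation controls (-0.35, adjusted p = 0.0963) or the poly-A controls (-0.52, adjusted p = 0.0632) also ended that of P3h2. The call of Krt23 ended in each such fit except that without vehicle replicate 2 (0.93 to 1.07 in the others). The call of Tnfrsf21 ended without vehicle replicate 1 or any dDAVP array (0.99 to 1.07). That of Tmem178 ended without vehicle replicate 1 or 2 or dDAVP replicate 1 or 2 (0.93 to 0.98). That of B3gnt7 ended without dDAVP replicate 2 (1.11, adjusted p = 0.0520). With the replicate number as a block, the calls of Rasl11a, Fras1, P3h2, Krt23 and Tmem178 ended as well.

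**Figure D1:**
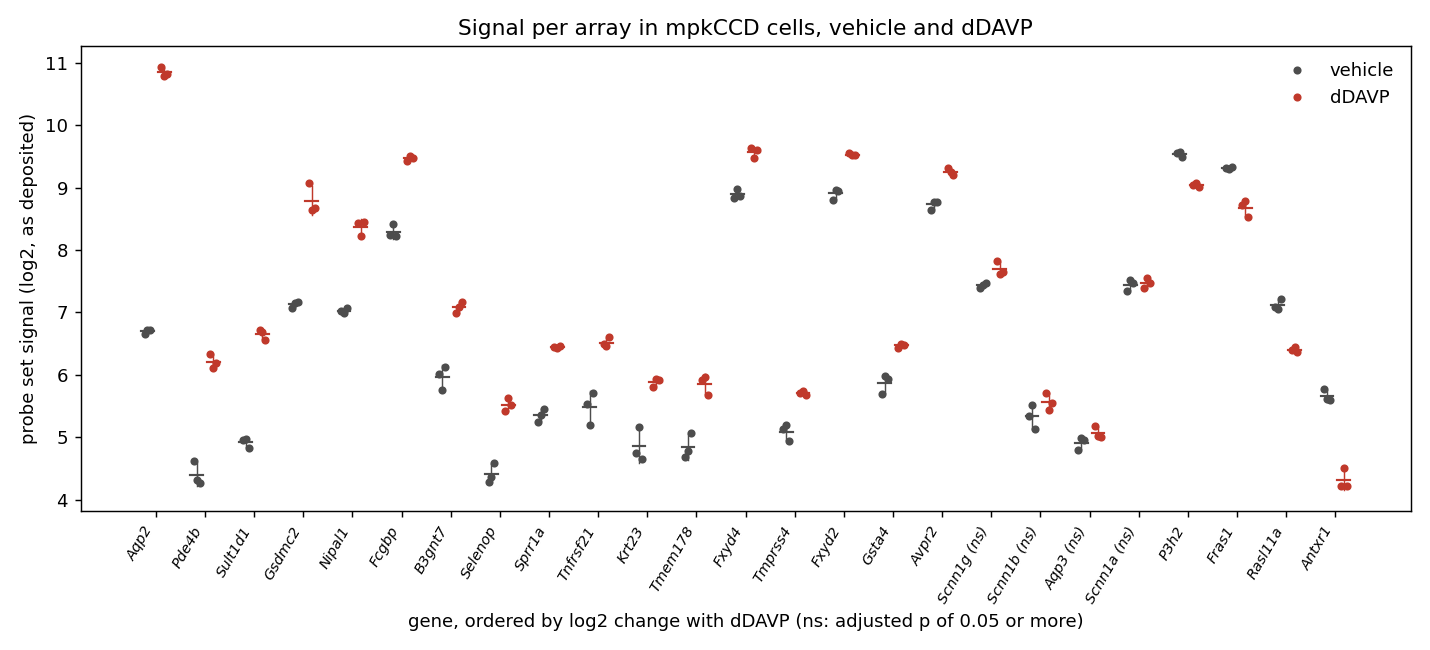
Probe set signal (log2, as deposited) on each array for the 25 genes named by rule, ordered from the largest rise to the largest fall; grey points are the 3 vehicle arrays, red points the 3 dDAVP arrays, horizontal lines are group means and vertical lines 1 SD. Aqp2 lies at 6.70 with vehicle and 10.85 with dDAVP, and the 4 genes marked ns (Scnn1g, Scnn1b, Aqp3, Scnn1a) did not pass the test.

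Counted by probe set, 61 changed, 53 higher and 8 lower, so 86.9% were higher. Of these 52 named 1 gene, 2 named several genes and 7 were unnamed, 4 of them higher and 3 lower. Scaling each array to its hybridisation controls, a setting chosen after the data were seen, moved the median change of all probe sets from 0.0039 to 0.15. Then 282 probe sets passed, 275 higher and 7 lower (97.5% higher). Lowering the dDAVP arrays by 0.146 gave 39 higher and 50 lower (43.8% higher). Leaving out 1 array, the count was 26 without vehicle replicate 1, 46 without vehicle replicate 2, 26 without vehicle replicate 3, and 25, 22 and 30 without dDAVP replicates 1, 2 and 3.

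**Figure D2:**
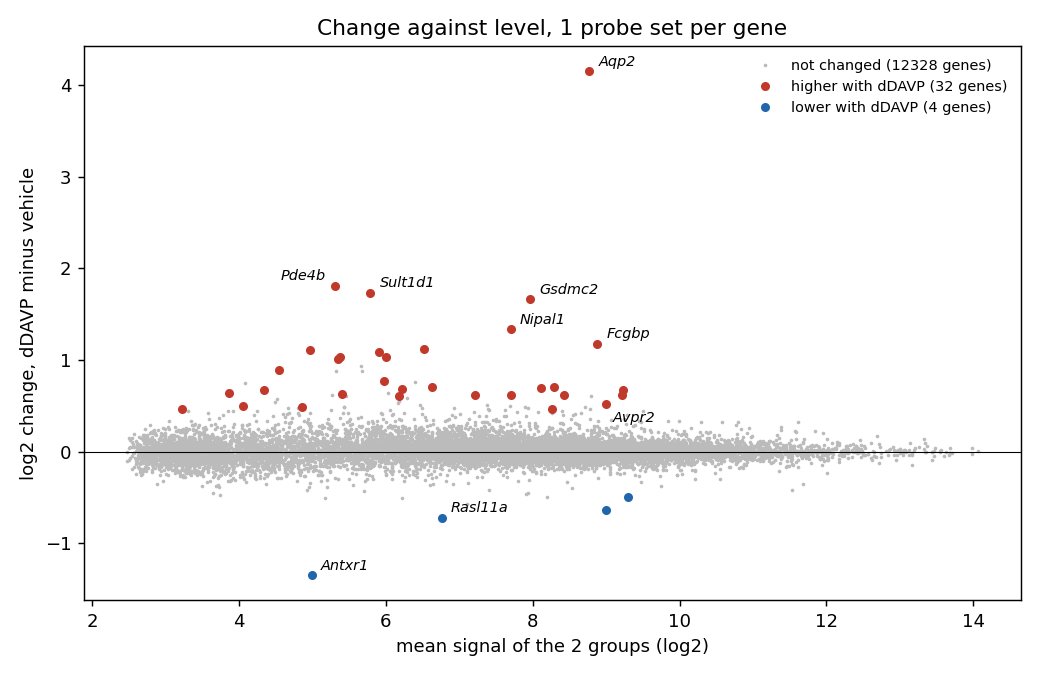
Log2 change (dDAVP minus vehicle) against the mean log2 signal of both groups, 1 point per gene for 12364 genes; red points are the 32 genes higher with dDAVP, blue points the 4 lower genes and grey points the rest. Aqp2 stands at 4.15, the next gene, Pde4b, at 1.81, and the median of all probe sets is 0.0039.

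Among the genes of principal cell water and ion transport, 4 of the 25 measured members rose, none fell (0) and 21 did not pass, with 5 higher when adjusted over the list alone. Besides Aqp2 these were the sodium pump regulators Fxyd4 (1.60-fold, adjusted p = 0.0116) and Fxyd2 (1.54-fold, adjusted p = 0.0137), and the membrane serine protease Tmprss4 (1.54-fold, adjusted p = 0.0271). All 3 Fxyd2 probe sets rose. The list as a whole was higher (median log2 change 0.15, camera adjusted p = 1.72e-06), a call that was lost, adjusted p = 0.0814, with an estimated correlation. Scnn1g, with 0.26, passed only over the list alone (adjusted p = 0.0425). The calls of Fxyd2 (0.57 to 0.64) and Tmprss4 (0.55 to 0.64) ended in every fit that left out 1 array except that without vehicle replicate 2. That of Fxyd4 (0.65 to 0.66) ended without vehicle replicate 1 or 3 or dDAVP replicate 1 or 3.

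The list of vasopressin receptor and cAMP signalling genes was not called by camera (median 0.02, camera adjusted p = 0.585), although 2 of its 35 measured members, Avpr2 and Pde4b, rose. Adjusted over the list alone, 3 were higher and 1 lower. The additional members, chosen after their values were seen, were the phosphodiesterase Pde4d (0.55 ± 0.12, adjusted p = 0.0251) and the receptor adaptor Arrb1 (-0.50 ± 0.12, adjusted p = 0.0251). Of the 29 measured early genes induced by cAMP and CREB, none passed over all probe sets by limma (0 genes). An unadjusted p below 0.05 was seen for 14, and 9 passed when adjusted over the list alone, 8 higher and 1 lower. The list was higher as a whole (median 0.17, 23 members with a positive and 6 with a negative change, camera adjusted p = 1.47e-05), but not at adjusted p = 0.0814 with an estimated correlation. Examples chosen after their values were seen are the nuclear receptor Nr4a1 (0.36 ± 0.058), the transcription factor Egr3 (0.37 ± 0.061) and the G protein regulator Rgs2 (0.62 ± 0.10). None of these passed over all probe sets on the brightest probe set (adjusted p = 0.0910, 0.0928 and 0.0928). A second Rgs2 probe set rose by 0.92 (adjusted p = 0.0172). The 1 member that was lower when adjusted over the list alone was Ppargc1a (-0.28 ± 0.071, limma adjusted p = 0.0175). The classic immediate-early genes Fos (-0.17 ± 0.12) and Egr1 (-0.12 ± 0.071) had negative values but did not pass, even over the list alone. Ppargc1a, Fos and Egr1 were also chosen after their values were seen.

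Mitosis genes were lower as a list (camera adjusted p = 5.45e-13, with adjusted p = 0.0929 with an estimated correlation). A negative change was seen in 32 of 33 measured members, with a median of -0.11, although no single member passed in limma (0 over all probe sets, 0 adjusted over the list alone, 7 at an unadjusted p below 0.05). Kif11, a spindle motor, was at -0.26 ± 0.067, the proliferation marker Mki67 at -0.22 ± 0.066 and the checkpoint kinase Bub1b at -0.17 ± 0.057, chosen after their values were seen. With arrays scaled to the hybridisation controls the median of this list was 0.04 against 0.15 for all probe sets, while camera still placed it below other genes (adjusted p = 1.35e-08). The DNA replication list was not called (median -0.03, adjusted p = 0.0938, 0 members at an unadjusted p below 0.05).

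Oxidative stress and glutathione genes were higher as a list (median 0.10, camera adjusted p = 1.05e-06, with adjusted p = 0.0938 with an estimated correlation). Among its 22 measured members the glutathione transferase Gsta4 alone (1) rose, by 1.52-fold at the edge of the threshold (adjusted p = 0.0499), while 6 were higher when adjusted over the list alone. Leaving out any 1 array ended the Gsta4 call (log2 change 0.52 to 0.66), as did quantile normalization (0.59, adjusted p = 0.0596), median centring (0.59, adjusted p = 0.0561) and a robust prior (0.61, adjusted p = 0.0584). The unfolded protein and amino acid response list was higher (29 members, median 0.08, camera adjusted p = 8.35e-04, with adjusted p = 0.0929 with an estimated correlation). In limma 0 members passed over all probe sets, 6 had an unadjusted p below 0.05 and 1, the amino acid transporter chain Slc3a2 (0.26 ± 0.055), passed when adjusted over the list alone. Sterol synthesis genes were higher (22 members, median 0.09, camera adjusted p = 8.08e-04), with adjusted p = 0.358 with an estimated correlation. This was the 1 list called by camera that fry, a test of whether each list alone moves, did not call (adjusted p = 0.0796). No member passed either over all probe sets or when adjusted over the list alone (0 and 0, with 4 at an unadjusted p below 0.05). EGF receptor family genes were higher (19 members, median 0.07, camera adjusted p = 0.00399), with adjusted p = 0.231 with an estimated correlation and adjusted p = 0.260 when only probe sets above the median level were used. No member passed over all probe sets (0), 5 had an unadjusted p below 0.05 and 3 were higher when adjusted over the list alone, led by the EGF receptor ligand Btc (0.88 ± 0.13, adjusted p = 0.0552 over all probe sets). Slc3a2 and Btc were also chosen after their values were seen.

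**Figure D3:**
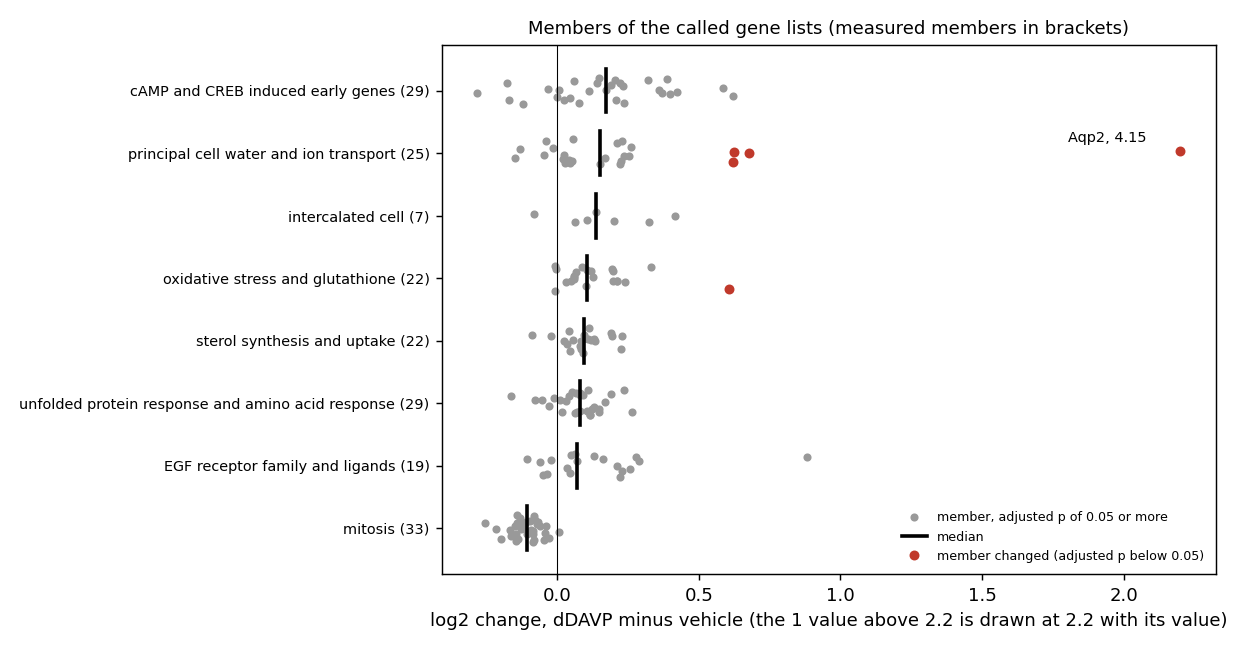
Log2 change (dDAVP minus vehicle) of each measured member of the 8 lists called by camera, red for members past the adjusted p threshold and grey for the rest, with a black bar at the list's median. Aqp2, at 4.15, is drawn at the right edge, and medians run from 0.17 for the early genes to -0.11 for mitosis, whose median was 0.04 with arrays scaled to the hybridisation controls (0.15 for all probe sets).

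Of the 6 lists of markers of other cell types, that of intercalated cells, the acid-base transporting neighbours of principal cells, was called higher on 7 of 21 members (median 0.14, camera adjusted p = 0.0165), with adjusted p = 0.204 with an estimated correlation. No member passed over all probe sets (0), and 2, the same number as at an unadjusted p below 0.05, were higher when adjusted over the list alone. These were the proton pump subunits Atp6v1b1 (0.32 ± 0.063) and Atp6v0a4 (0.42 ± 0.12), chosen after their values were seen. The call was lost without vehicle replicate 2 (median 0.13, adjusted p = 0.0756) and without dDAVP replicate 1 (0.10, adjusted p = 0.0627). Markers of proximal tubule (9 measured, median 0.01), thick ascending limb and distal convoluted tubule (5, 0.05), fibroblast and smooth muscle (3, 0.06), endothelium (3, -0.02) and leukocytes (8, 0.03) were not called and held no changed gene (0 each). An unadjusted p below 0.05 was seen for 2 of these 28 members, and 1 was higher when adjusted over the list alone.

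Another 13 lists were not called by camera and held no changed member over all probe sets (0 each). Of their 323 listed members measured, counted once per list, 21 were higher and 19 lower at an unadjusted p below 0.05, and 4 were higher and 5 lower when adjusted over the list alone. The median log2 change was -0.04 for collecting duct transcription factors, 0.02 for AQP2 vesicle trafficking, -0.01 for tight and adherens junctions, 0.0028 for mesenchymal and TGF-beta responsive genes, 0.06 for NF-kB and cytokine genes and 0.02 for interferon response genes. It was -0.04 for glycolysis and hypoxia, 0.03 for oxidative phosphorylation, 0.04 for fatty acid oxidation, 0.04 for the osmotic response, 0.02 for local paracrine regulators, 0.05 for p53 targets and apoptosis and 0.06 for the circadian clock. The lowest camera adjusted p among the 20 lists it did not call was 0.0686. For junctions, mesenchymal genes, paracrine regulators, proximal tubule and endothelium, the median, the mean and the direction of the test did not all have the same sign. Regrouping the 6 arrays across treatments gave up to 6 lists called by camera at the preset correlation, where the treatment gave 8. Such regroupings still hold part of any treatment effect. Fry called 10 lists, 7 of them shared with camera. The 3 it added were vasopressin receptor and cAMP signalling (adjusted p = 0.0190), AQP2 vesicle trafficking (0.0267) and NF-kB and cytokine genes (0.0433).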

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

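The scalings to hybridisation or poly-A controls and the count of genes by any changed probe set were chosen after the data were seen. The log2 change of Aqp2 passed under every alternative that tests it, between 4.11 and 4.30. Of the 61 probe sets, 53 higher, 8 lower and 36 genes, the counts moved as follows. With only probe sets above the median level, 95 passed, 21 of them lower, in 68 genes. Fewer probe sets were tested there and the prior was fitted to them alone, and what raised the count was not tested. Above the olfactory receptor level 13 were lower. A trended prior gave 146 probe sets, 116 higher and 30 lower, in 99 genes. A threshold of 0.01 left 23, 19 higher and 4 lower, in 13 genes, as a stricter threshold must. The mean of each gene's probe sets gave 91 genes. Scaling to the hybridisation controls gave 282 probe sets, 275 higher, in 154 genes, and scaling to the poly-A controls gave 5 lower. Leaving out 1 array, which also removes a degree of freedom, gave 22 to 46 probe sets, 18 to 40 higher, 4 to 6 lower, and 12 to 29 genes. The lowest counts came without dDAVP replicate 2 (22 probe sets, 12 genes), and each array but vehicle replicate 2 moved the counts of probe sets and genes by over 1.5 times. Scnn1a, never past the threshold, ranged from -0.026 to 0.066 in these fits, with a negative sign without vehicle replicate 1 (-0.026) and without dDAVP replicate 2 (-0.016). Camera with an estimated correlation called 0 of the 28 lists, against 8 at the preset correlation and 10 by fry, and the other settings called 7 to 11. Apart from changes explained by construction, the cause was not tested.

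The labels do not say whether the replicate numbers pair the samples, and 3 arrays per group are too few to decide it. Deviations from the group mean correlated at 0.20, 0.046 and -0.052 between arrays of the same number. The 0.20, for replicate 1, was the highest between any vehicle and any dDAVP array. However, vehicle replicate 2 correlated best with dDAVP replicate 3 (0.17). The fit with the replicate block gave 24 probe sets, 21 higher and 3 lower, in 12 genes. Of the 21 changed genes named by rule, 9 passed under each alternative in which they were tested, and over all 304 pairs of gene and alternative 236 kept the call, 68 lost it and 0 changed direction. Leaving out 1 array ended 5 to 10 of these 21 calls. The replicate block ended 10 of them, those of Avpr2, Fras1, P3h2, Gsta4, Krt23, Tmem178, Fxyd2, Fxyd4, Tmprss4 and Rasl11a. The floors planned for linear signals were not run because the values are on a log2 scale, and no second Aqp2 probe set was measured. The simulated runs recovered 78.8% of changes of 0.5 log2 units and 13.2% of 0.3, so smaller changes were mostly out of reach of 3 arrays per group.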

Other observations

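All genes in the next 2 paragraphs were chosen after their values were seen. The changed genes that the naming rule did not reach were higher with dDAVP and included the membrane mucin Muc4 (log2 change 0.89, adjusted p = 0.00635), the lipopolysaccharide-binding protein Lbp (0.62, adjusted p = 0.0106) and the gap junction protein Gjb1 (0.50, adjusted p = 0.0345). Enzymes among them were the sphingosine kinase Sphk1 (0.46, adjusted p = 0.0243), the sphingolipid desaturase Degs2 (0.70, adjusted p = 0.0159), the phosphatidate phosphatase Lpin2 (0.71, adjusted p = 0.0159) and the branched-chain aminotransferase Bcat1 (0.70, adjusted p = 0.0137). A dimmer Sphk1 probe set did not pass (0.22, adjusted p = 0.668). Of the dimmer Lpin2 probe sets, that at 0.81 passed (adjusted p = 0.00670), and those at 0.38 and 0.57 did not (adjusted p = 0.122 and 0.0963). Of the dimmer Bcat1 probe sets, that at 0.50 passed (adjusted p = 0.0412) and that at 0.52 did not (adjusted p = 0.0913). The transcription factor Cebpd (0.67) passed at the edge of the threshold (adjusted p = 0.04997). The Gjb1 probe set was dim, at 3.81 in vehicle cells and 4.31 in dDAVP cells, where the highest olfactory receptor probe set had 3.56. Counting a gene when any of its probe sets changed added 6 genes to the 36. For the transglutaminase Tgm2, 2 of 4 probe sets rose (0.67 and 0.58), and the Wnt receptor Fzd4 (0.47, adjusted p = 0.0399), the mannosidase Man1a (0.61, adjusted p = 0.0166) and the fatty acid elongase Elovl6 (0.75, adjusted p = 0.0218) each had a probe set that rose. The brighter probe sets of these 4 genes did not pass: 2 of Tgm2 (0.45 and 0.30, adjusted p = 0.109 and 0.461), 1 of Fzd4 (0.46, adjusted p = 0.236), 1 of Man1a (0.38, adjusted p = 0.0553) and 2 of Elovl6 (0.24 and 0.18, adjusted p = 0.328 and 0.577), whose change of 0.75 came from the dimmest of 3.

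Within lists that camera did not call, some members passed only when adjusted over the list alone (adjusted p in brackets). Of the 25 mesenchymal and TGF-beta responsive genes, 5 did: the basement membrane collagens Col4a1 (-0.29, 0.0142) and Col4a2 (-0.34, 0.0142), the matrix protein Sparc (-0.36, 0.0105) and the growth factor Tgfb2 (-0.37, 0.0200) were lower, and Tgfb3 (0.41, 0.0105) was higher. Over all probe sets these had adjusted p from 0.111 to 0.307 in limma, so none passed. Jun, among the collecting duct transcription factors, was lower (-0.38, 0.0180). The clock gene Bhlhe40 (0.35, 0.00512) and the interferon-induced Ifit1 (0.42, 0.0444) and Ifit3 (0.26, 0.0444) were higher. Aqp5, the water channel gene next to Aqp2 in the mouse genome, had a log2 change of 0.33 that did not pass (adjusted p = 0.313).

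The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The treatment was the 1 split that reached 61 probe sets, 53 higher, 8 lower and 36 genes, and the highest count in another split was 0 for each in limma. Each other split mixes the treatments, so a treatment effect widens the spread within its groups and hinders calls of such probe sets. Part of the effect also stays in the contrast, so the counts from other splits are not counts without an effect. For lists called by camera, the treatment gave 8 and the highest other split 6, again with 1 split as high. At an unadjusted p below 0.05 the treatment gave 965 genes, where a share of 0.05 of all genes is 618. Another split, vehicle replicates 1 and 3 with dDAVP replicate 1 against the rest, gave 1115. The remaining splits gave 262 to 486. The split with 1115 also keeps part of the treatment contrast, as each other split does. The labels name no batch, so what those arrays share is not known here.

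The tests in the paragraphs below were chosen after the result was seen, except that on gene family members among neighbours. More probe sets rose than fell (86.9% of 61). Scaling in the deposited values could make such an excess. The share of higher calls was 84.1% after quantile normalization and 83.3% after median centring, but these settings moved the median change of all probe sets only from 0.0039 to -0.0027 and -0.0083, so they decide nothing. The share was 89.8% with arrays scaled to the poly-A controls (44 higher, 5 lower, median change -0.020) and 97.5% when scaled to the hybridisation controls (275 higher, 7 lower, median change 0.15). The dDAVP arrays were therefore lowered by 0.146 log2 units, the change of the poly-A controls plus 2 SE. That SE rests on 3 arrays per group with SDs of 0.10 and 0.019, so the controls do not exclude a larger lowering. With that lowering, 39 of 89 calls were higher (43.8%, exact 95% interval 33.3% to 54.7%), so scaling stays open for the excess over all calls. Among genes changed at least 2-fold, each counted once, 12 of 13 were higher as deposited and 6 of 7 after the lowering (85.7%, 42.1% to 99.6%), too few to decide. A floor under dim probe sets could hide falls, but among the brighter probe sets, those above the median level, 74 of 95 calls were higher (77.9%, exact 95% interval 68.2% to 85.8%). Rises thus outnumbered falls also among probe sets where a floor should matter less. The exact intervals over probe sets count each as independent. Probe sets of the same gene are not, and all were read on the same arrays, so these intervals are too narrow. The brighter calls were not counted by gene in this test, so the floor as the whole cause is less likely but not excluded. An effect of dDAVP itself stays open as a hypothesis, as does any unlabelled difference in handling between the groups.

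The hybridisation controls were lower on dDAVP arrays by 0.15 log2 units (change -0.148 ± 0.060, SE), in 18 of 18 probe sets, while no control probe set passed the limma threshold (0 of 62). More messenger RNA per total RNA in treated cells is a candidate explanation, but it predicts a like fall of the poly-A controls, which changed by 0.024 ± 0.061. With SEs of 0.060 and 0.061 on 3 arrays per group, a like fall is not excluded. A smaller amount of control mixture, or more labelled material, on the dDAVP arrays would lower the hybridisation controls alone, as seen, and may be the source. With 3 arrays per group the exact p of 0.1 is the smallest possible, so the shift itself is not established.

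A pair of changed genes had probe sets that differed from each other, the only 2 past the threshold among 10733 pairs of probe sets in 5977 genes. For Pde4b 3 probe sets rose and the fourth did not (difference -1.86 ± 0.13, adjusted p = 0.00287). That probe set has a mean of 3.60, near the highest olfactory receptor probe set (3.56), so it may carry no signal to change. For Antxr1 a probe set with a mean of 4.64 did not follow the fall of the other (difference 1.44 ± 0.12, adjusted p = 0.00372). Its level lies between the olfactory receptor probe sets and the median of all probe sets (6.72), so lack of signal and transcripts that respond differently cannot be told apart.

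A hypothesis was that genes beside the raised genes rise with them. The nearest measured neighbours on either side of the 32 raised genes, 61 in all, had a median change of 0.040 with 44 above 0, which lies at the 98.8th percentile of 10000 random gene sets, and at the 98.7th with sets matched on level. Leaving out 5 neighbours that share the start of the symbol with their raised gene gave the 97.7th percentile (56 left, median 0.037), so related family members may not account for it alone. The next neighbours out had a median of 0.012, at the 50.9th percentile, against 0.012 for all genes in the pool. The raised genes were chosen and their neighbours tested on the same arrays, so this stays a hypothesis.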
